A study of Mus musculus with 16 samples.

How the data were processed

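The values are the FPKM deposited by the authors, 1 file per library with 24341 gene symbols each, none listed more than once. Per the submitters' processing notes reads were aligned with STAR to mm10 and quantified with Cufflinks and Cuffdiff, whose versions are not given in the sources used here. Per the labels total RNA was made into libraries with the NEBNext Ultra II Directional kit. Reads were not analysed here. The labels do not spell out 3dai or G2, and the groups are called by those suffixes.

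Libraries, comparisons, gene lists and alternatives were fixed before the data were examined. FPKM of 16 libraries were taken to log2(FPKM + 1), genes with at least 1 FPKM in 2 libraries were kept (12954), and all groups were fitted together with limma 3.58.1 (R 4.3.3) with a variance trend. Every gene p is from limma's moderated test, adjusted by Benjamini-Hochberg over the genes of a comparison, with 0.05 as the limit for a call. An interaction is the genotype difference in 3dai or G2 minus that with no suffix. Lists were tested with camera at a preset correlation of 0.01 and again with the correlation estimated, adjusted over the lists of a comparison; 33 lists were written and the 26 with at least 5 genes measured were tested. Red blood cell, adipocyte and neutrophil markers had too few genes: in 3dai against no suffix 0 were higher and 3 lower for red blood cells in each genotype, 0 and 2, and 0 and 3 for adipocytes, and 0 and 0, and 1 and 1 for neutrophils. A count adjusted over a list alone uses the p of its own genes. Every interval is from a bootstrap over the genes of a list, which are not independent, and leaves out the spread between libraries.

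Genes were named by a rule fixed with the design. Trp53, Dmd, Terc and the sort markers are always given. From each comparison come the 8 largest rises and 8 largest falls that were called, had a mean of 5 FPKM in the higher group and no overlap between groups. From each list that passed or had 2 called genes come the 2 largest rises and 2 largest falls, and from each interaction 5 in each direction. Small RNA names and unnamed loci were left out of the rule. Snora33, Taco1, Plk2, Sesn2, Eda2r, Mdm2, Fos, Pax7 and other genes given outside this rule were chosen after the values were seen. Results of some genes that the rule names are not reported here.

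Exact zeros are common: 7919 genes are at 0 in every library, and 94 genes with a median over 20 FPKM are at 0 somewhere. The zeros of Snora33, Cdkn3, Taco1, Glrp1, Prss8 and Ccl19 carry the status OK. A listed 0 is not taken as absence. Sums of FPKM ran from 423303 to 616485, and Mir6236, a small RNA name, made up 9.81% and 10.1% of the sum in p53KO_3dai replicates 2 and 3 (0.277% to 2.36% in the others). Correlations within groups were 0.957 to 0.981.

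The fit was tested on simulated data made from these libraries, with 200 of 12954 genes changed. The 200 were drawn only from genes above about 5 FPKM in the p53WT group of the comparison. At 2-fold 36% were recovered for p53KO against p53WT with no suffix, 27% in 3dai and 13% in G2, and at 4-fold 86%, 91% and 80.5%. Of the calls 5.26%, 6.90% and 16.1% were wrong at 2-fold and 6.01%, 8.08% and 3.59% at 4-fold. Recovery was not measured at all for genes below that level, so these shares are no measure of sensitivity over all 12954 genes. Whether they hold where the libraries of a group differ strongly, as in p53KO_3dai, was not tested.

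Alternatives were a pseudocount of 0.1, no filter, a filter at a mean of 5 FPKM, quantile normalization, median-of-ratios scaling, small RNA and mitochondrial names left out, array weights, a fit of only the groups compared, the replicate number as a block, and each library left out in turn. Values of status FAIL or LOWDATA set to missing, p53KO_3dai replicate 1 alone in its group, lists under median-of-ratios scaling and lists without p53KO replicate 3, p53KO_3dai replicate 1 or p53KO_3dai replicates 2 and 3 were added after the data had been seen, as was the comparison of G2 with 3dai.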

Results

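RNA of sorted mouse muscle cells was measured in 16 libraries of 6 groups: p53WT (n = 3), p53KO (n = 3), p53WT_3dai (n = 3), p53KO_3dai (n = 3), p53WT_G2 (n = 2) and p53KO_G2 (n = 2). Per the labels the cells were sorted as positive for CD34 and alpha-7 integrin and negative for CD31, CD11b, CD45 and Sca-1, from C57BL/6 mice of 2 to 3 months. The groups with no suffix and the G2 groups came from hind limb muscles and the 3dai groups from the tibialis anterior, so a 3dai difference from the groups with no suffix is also a difference of muscle. Each library holds FPKM for 24341 genes, of which 10240 to 11574 reach 1 FPKM, and sequencing depth is unknown from the files. Nothing in the labels says that replicates are separate animals, so every p measures only the spread between these samples. Differences are on the log2(FPKM + 1) scale, which understates changes of genes with low values, and group values are mean FPKM ± SD.

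Trp53, the gene named by the knockout, had lower transcript in every p53KO library than in any p53WT library of the same suffix. With no suffix its FPKM was 40.0, 53.9 and 48.1 in p53WT and 6.34, 12.2 and 7.17 in p53KO. In 3dai it was 134, 135 and 161 against 41.3, 45.7 and 34.9, and in G2 71.0 and 59.9 against 16.8 and 19.8. The remaining transcript is measured over the whole gene, and which part of it the knockout removes is not given in the sources used here. Dmd, which codes dystrophin, did not pass between genotypes (log2 difference 0.11, 0.35 and 0.19 with no suffix, in 3dai and in G2). The series title names a Duchenne model, but the labels give no Dmd genotype for these libraries, so what the Dmd values mean is open. Terc, the telomerase RNA, is listed at 0 in all 16 libraries. The genes of the sort followed the labels: Cd34 lay between 27.1 and 140.3 FPKM and Itga7 between 81.1 and 317, while Pecam1 reached at most 2.09, Itgam 0.286, Ptprc 0.00898 and Ly6a 6.60.

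**Figure D1:**
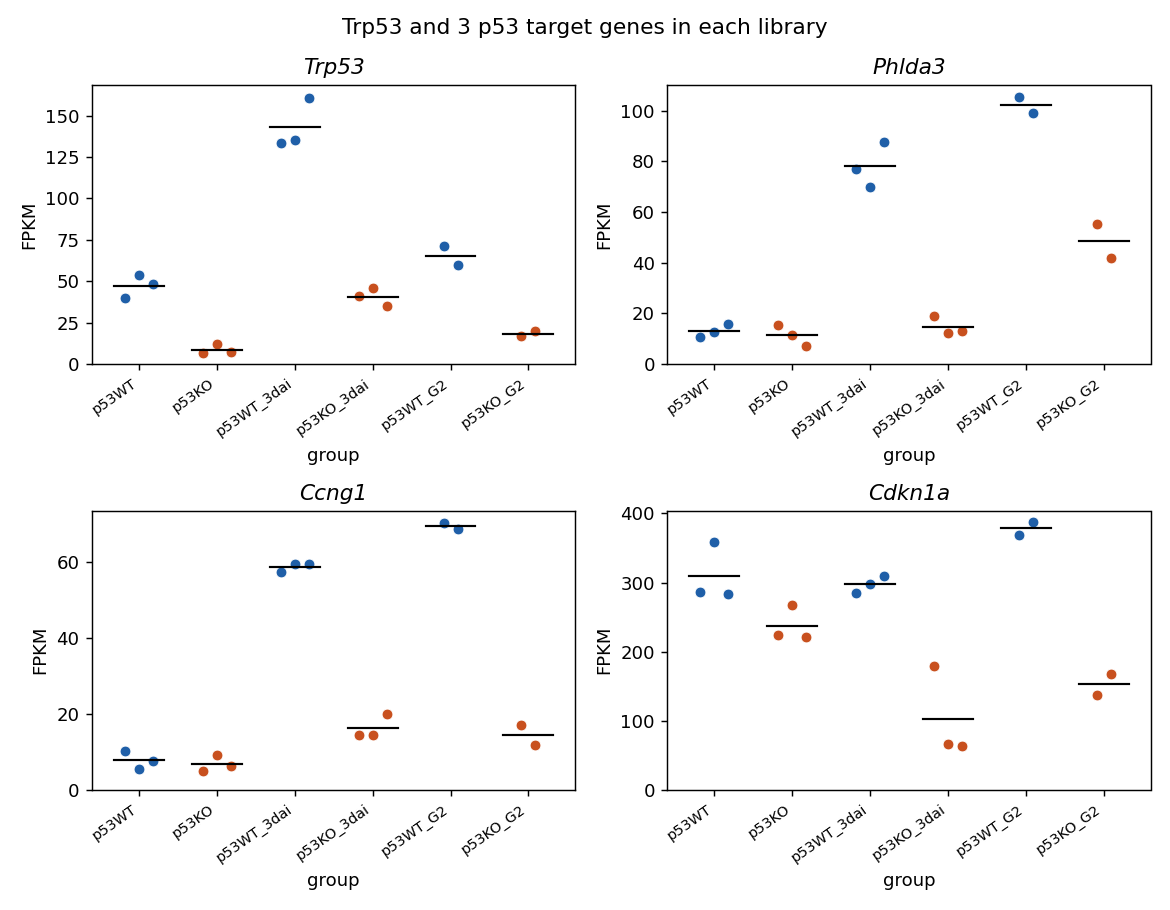
FPKM of Trp53, Phlda3, Ccng1 and Cdkn1a in each library (vertical axis, FPKM) by group (horizontal axis); each point is 1 library, blue p53WT and orange p53KO, and each line is the group mean. Phlda3 averaged 78.1 FPKM in p53WT_3dai and 14.6 in p53KO_3dai.

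Which transcripts differ between p53KO and p53WT cells with no suffix? Trp53, which codes the transcription factor p53, fell with p53KO, from 47.3 ± 7.01 to 8.58 ± 3.19 FPKM (n = 3 each; log2 difference -2.37, SE 0.22, adjusted p = 0.000188). It was the only gene called among 12954, and with only the groups compared in the fit 0 were called. Cdkn1a, the p53 target that codes a cyclin-dependent kinase inhibitor, stood at 224, 267 and 221 FPKM in p53KO and 286, 359 and 283 in p53WT and was not called. Of 44 p53 target genes 0 were called, also with adjustment over the list alone, their median difference was 0.00, and the list test gave adjusted p = 0.861. By limma's test 512 genes had an unadjusted p under 0.05, where 648 would by chance, and in 872 genes the groups did not overlap, where chance gives 10% of genes.

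The p53 targets with the smallest p with no suffix pointed both ways, and none passed. Gdf15, a secreted stress factor, was at 12.3 ± 4.81 FPKM with p53KO and 5.02 ± 2.82 with p53WT (log2 difference 1.19, SE 0.50, adjusted p = 1). Polk, a translesion polymerase, differed by 0.72, Ckap2, a spindle protein, by -0.74, and Aen, a nuclease of apoptosis, by -0.64. As lists, Notch pathway genes (median 0.34, adjusted p = 0.0474), immediate early genes (0.34, adjusted p = 0.0138), heat shock genes (0.31, adjusted p = 0.0138) and ribosomal proteins (0.11, adjusted p = 0.0138) were higher with p53KO. In each, 0 genes were called and adjusted p = 0.925 with an estimated correlation. Without p53KO replicate 3 these adjusted p were 0.829, 0.994, 0.574 and 0.15 at the preset correlation, and interferon response genes passed instead (adjusted p = 0.044). The estimated correlation was not run without p53KO replicate 3. The library p53KO replicate 3 held Fos, an immediate early transcription factor, at 4273 FPKM (1265 and 1164 in the other p53KO libraries) and Pax7, the transcription factor of muscle stem cells, at 97.1 (27.7 and 28.2).

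What does p53KO change in 3dai cells? Phlda3, a p53 target that restrains Akt, fell with p53KO from 78.1 ± 8.93 to 14.6 ± 3.77 FPKM (n = 3 each; log2 difference -2.36, SE 0.26, adjusted p = 0.00163). Ccng1, a p53-induced cyclin, fell from 58.6 ± 1.23 to 16.2 ± 3.25 (-1.81, SE 0.25, adjusted p = 0.0124), and Cdkn1a fell from 297.5 ± 12.9 to 102 ± 66.1 (-1.71, SE 0.29, adjusted p = 0.0369). Pmaip1, which promotes apoptosis, fell from 33.7 ± 7.68 to 11.4 ± 3.38 (-1.50, adjusted p = 0.0277), and Slc19a2, a thiamine transporter, from 30.0 ± 7.87 to 9.98 ± 3.26 (-1.51, adjusted p = 0.0369). Trp53 itself fell from 143 ± 15.2 to 40.6 ± 5.44 (-1.80, SE 0.22, adjusted p = 0.0036).

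Of 12954 genes 11 were called in 3dai, 1 higher and 10 lower with p53KO, and with array weights 804 were, 106 higher and 698 lower. The higher gene was Pigb, of GPI anchor synthesis, at 4.33, 6.42 and 8.41 FPKM against 1.16, 0.442 and 0 (log2 difference 2.30, SE 0.35, adjusted p = 0.0238). Trp53inp1, a p53-induced nuclear protein, fell from 9.36 ± 2.70 to 0.915 ± 1.02 FPKM (-2.53, SE 0.41, adjusted p = 0.0298). Ephx1, an epoxide hydrolase, fell to 1.40, 0.344 and 0 FPKM against 2.87, 6.13 and 4.63 (adjusted p = 0.0456). Glrp1, a glutamine-repeat protein, was listed at 0 in the 3 p53KO_3dai libraries against 2.22, 1.78 and 3.08 (adjusted p = 0.0263), and Prss8, a membrane serine protease, was listed at 0 against 3.37, 1.76 and 2.04 (adjusted p = 0.0226). By limma's test 1151 genes had an unadjusted p under 0.05, and 1552 did not overlap between the groups against 10% of genes by chance.

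As a list, the p53 targets were lower with p53KO in 3dai (median -0.80, adjusted p = 5.83e-17, or 0.0511 with an estimated correlation), with 0 genes higher and 7 lower of 44, or 23 lower when adjusted over the list alone. Senescence genes were also lower (median -0.48, 0 higher and 1 lower, 3 alone, adjusted p = 5.5e-05, or 0.509 with an estimated correlation). The senescence gene called was Cdkn1a, and the list shares Cdkn1a and Gdf15 with the p53 targets. Mitosis genes were higher by a median of 0.25 with 0 called (adjusted p = 0.000315, or 0.866 with an estimated correlation). So were interferon response genes (0.15, adjusted p = 0.0254, 0.889 estimated) and heat shock genes (0.18, mean 0.49, adjusted p = 0.0175, 0.951 estimated). Apoptosis genes passed as lower, with 0 higher and 1 lower, or 5 alone (adjusted p = 0.0175, 0.345 estimated), and 6 of them are also p53 targets. Their mean was -0.41 and their median -0.02, which turns to 0.04 under median-of-ratios scaling. The 3 p53KO_3dai libraries were not alike. By mean log2(FPKM + 1), immediate early genes stood at 4.76, 3.93 and 4.11 (4.40 to 4.55 in p53WT_3dai) and heat shock genes at 6.70, 7.50 and 7.55 (6.70 to 6.82). Higher in replicate 1 were Schwann cell markers (2.16, 1.12 and 0.822, with 0.991 to 1.37 in p53WT_3dai) and pericyte markers (1.83, 0.991 and 0.935, with 0.964 to 1.40). So were extracellular matrix genes (4.23, 3.23 and 3.09, with 3.48 to 3.85). Macrophage markers (0.438, 1.41 and 0.971, with 0.777 to 1.23 in p53WT_3dai) were lower in replicate 1. Mature fibre markers (2.17, 2.38 and 2.33) were lower too, but inside the p53WT_3dai range of 1.95 to 2.60. Plk2, a p53-induced kinase, stood at 200, 20.6 and 24.1 FPKM, Sesn2, a stress-induced p53 target, at 27.1, 0 and 1.19. Eda2r, a p53-induced receptor, stood at 14.1, 0.184 and 0.624, and Fas, a death receptor, at 6.24, 0 and 0. Mdm2, the ligase that degrades p53, stood at 30.1, 26.0 and 24.8 against 55.5, 60.6 and 63.4 in p53WT_3dai and was not called (adjusted p = 0.0508).

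Leaving out p53KO_3dai replicate 1 raised the 11 calls to 512 (41 higher, 471 lower), while leaving out p53KO_3dai replicate 2 or 3 gave 4 and 5, and p53WT_3dai replicate 1 or 3 gave 3 and 2. Trp53 and Phlda3 stayed called whichever library was left out, but with only the groups compared in the fit 0 of the 11 genes were called. Without p53WT_3dai replicate 3 the adjusted p became 0.239 for Ephx1, 0.216 for Cdkn1a, 0.203 for Slc19a2, 0.191 for Pmaip1 and 0.155 for Glrp1. It became 0.153 for Pigb and 0.0649 for Ccng1, Trp53inp1 and Prss8. Cdkn1a, Ephx1 and Trp53inp1 kept the call only without p53KO_3dai replicate 1 (adjusted p otherwise 0.132 to 0.216, 0.0641 to 0.239 and 0.0649 to 0.146). The p53 target genes had a median of -0.97 with 17 lower without p53KO_3dai replicate 1 (adjusted p = 7.97e-16). Their median was -0.30 without replicates 2 and 3, which leaves 1 library in the group. With all 3 it was -0.80, so most of the size came from replicates 2 and 3. Without replicates 2 and 3 the medians were 0.043 for mitosis, 0.068 for senescence, -0.049 for heat shock and -0.0045 for apoptosis genes. Immediate early genes (adjusted p = 0.00364) and extracellular matrix genes (adjusted p = 0.00161) passed only without replicate 1, at the preset correlation, and the estimated one was not run there.

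**Figure D2:**
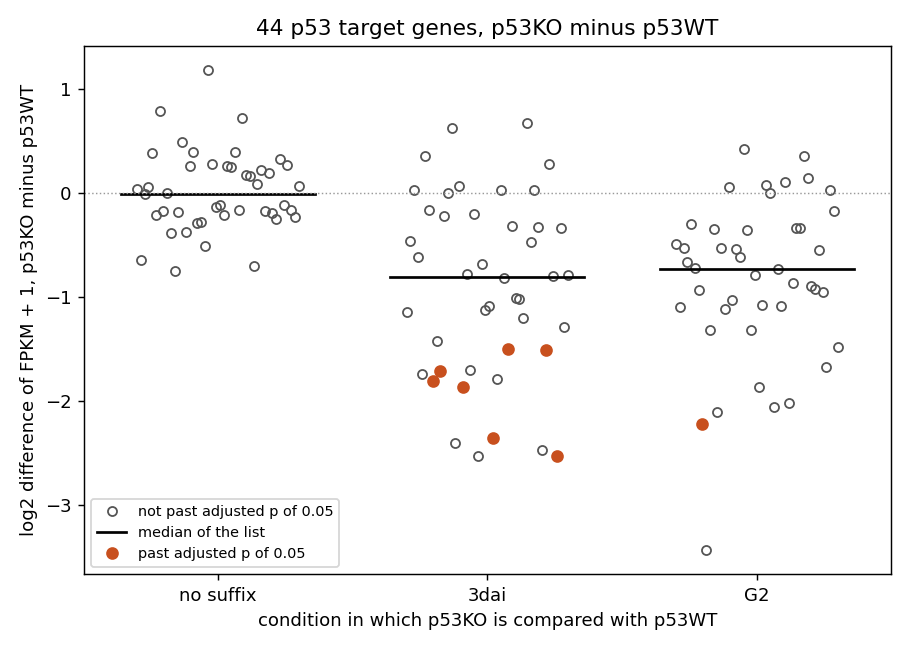
Log2 difference of p53KO minus p53WT on the log2(FPKM + 1) scale (vertical axis) for 44 p53 target genes (points) with no suffix, in 3dai and in G2 (horizontal axis). Filled points are genes called at adjusted p under 0.05 (0, 7 and 1), and the line is the median (0.00, -0.80 and -0.73).

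What does p53KO change in G2 cells? Ccng1 fell with p53KO from 69.5 ± 1.05 to 14.4 ± 3.60 FPKM (n = 2 each; log2 difference -2.22, SE 0.31, adjusted p = 0.0125), and Trp53 fell from 65.4 ± 7.86 to 18.3 ± 2.17 (-1.78, SE 0.27, adjusted p = 0.0181). Cdkn3, a phosphatase of cyclin-dependent kinases made in dividing cells, stood at 9.97 and 14.7 FPKM with p53WT and at 0 and 0.0844 with p53KO (adjusted p = 0.000779). Snora33, a small nucleolar RNA, was at 91.6 and 167 against 0 and 0 (adjusted p = 1.28e-08), and Ccl19, a chemokine, at 5.65 and 5.50 against 0 and 0 (adjusted p = 0.019). Higher with p53KO were Cldn5, a tight junction protein of endothelium, at 3.93 and 7.26 against 0.803 and 0.0391 (2.22, SE 0.38, adjusted p = 0.0452), and Cd7, a lymphocyte antigen, at 3.45 and 2.41 against 0 and 0 (adjusted p = 0.0177). So were the protease inhibitor Serpina3g at 4.01 and 3.36 against 0 and 0.34 (adjusted p = 0.0236) and Art1, an ADP-ribosyltransferase of muscle, at 4.33 and 4.88 against 0 and 0.86 (adjusted p = 0.0236).

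These are the 9 genes called in G2, 4 higher and 5 lower, and 631 genes had an unadjusted p under 0.05. Without p53WT_G2 replicate 1 or 2, or p53KO_G2 replicate 1, the count was 3, 3 and 4. Trp53 itself lost its call when either p53WT_G2 library (adjusted p = 0.221 and 0.0818) or either p53KO_G2 library (0.163 and 0.0747) was left out, with log2 differences of -1.66 to -1.91. Ccng1 lost it without p53WT_G2 replicate 1 (0.157), p53WT_G2 replicate 2 (0.0818) or p53KO_G2 replicate 2 (0.0879), and Ccl19, Cldn5 and Serpina3g (0.221, 0.0818, 0.16 and 0.0793) lost it whichever library was left out. Cd7 kept it only without p53KO_G2 replicate 2 (0.0344) and Art1 only without p53WT_G2 replicate 2 (0.0264), while Cdkn3 and Snora33 kept it in all 4 cases. With only the groups compared in the fit 0 genes were called in G2. Cdkn1a stood at 137 and 168 FPKM with p53KO against 369 and 388, and Phlda3 at 55.2 and 41.8 against 105 and 99.2, neither called. Zmat3, an RNA-binding p53 target, was at 3.32 ± 0.46 against 11.1 ± 2.04 (-1.48, SE 0.32, adjusted p = 0.179), Psrc1, a spindle protein, differed by -2.02 (adjusted p = 0.309), and Cd80, a costimulatory ligand, by -3.44 (adjusted p = 0.0595).

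The p53 targets were lower with p53KO in G2 as a list (median -0.73, adjusted p = 4.94e-17, or 0.0252 with an estimated correlation), with 0 higher and 1 lower of 44, or 16 lower when adjusted over the list alone. Tenocyte marker genes, of a cell type outside the sort, were lower too (10 genes, median -1.16, adjusted p = 4.4e-09, or 0.00936 with an estimated correlation) with 0 called, or 3 lower alone. Among them Thbs4, a matrix protein of tendon, stood at 308 and 355 FPKM in p53WT_G2 against 153 and 145, and Tnmd, a tendon membrane protein, at 39.7 and 54.3 against 16.1 and 23.1. Kera, a keratan sulfate proteoglycan, was at 9.69 and 15.7 against 5.81 and 5.59, and Comp, a cartilage matrix protein, at 5.48 and 7.00 against 3.02 and 1.06. Pericyte markers (median -0.63, adjusted p = 0.000688) were lower with 0 called and adjusted p = 0.516 with an estimated correlation. DNA replication genes (0.36, adjusted p = 7.44e-06, 0.357 estimated), mitosis genes (0.28, adjusted p = 8.88e-05, 0.516 estimated) and ribosomal proteins (0.12, adjusted p = 0.00886, 0.761 estimated) were higher as lists with 0 called. Differentiation genes of muscle (-0.28, adjusted p = 0.013, 0.761 estimated) and apoptosis genes (-0.22, adjusted p = 0.0359, 0.357 estimated) were lower, again with 0 called. Mean log2(FPKM + 1) of the mitosis genes was 5.24 and 4.69 in p53KO_G2 and 4.64 and 4.68 in p53WT_G2, so the higher value came from p53KO_G2 replicate 1. The same library stood out in DNA replication genes (4.98 and 4.45 against 4.31 and 4.40) and in pericyte markers (3.86 and 4.76 against 4.98 and 5.13).

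Does the effect of p53KO differ between 3dai and no suffix? In the interaction test 0 genes were called, by limma's test with 777 at an unadjusted p under 0.05. The smallest p belonged to Pigb (2.79, SE 0.50, adjusted p = 0.315) and Ptcd3, a mitochondrial translation protein (1.17, adjusted p = 0.468), on the higher side. On the lower side were Phlda3 (-2.15, SE 0.36, adjusted p = 0.315), Gdf15 (-3.72, adjusted p = 0.379), Apip of methionine salvage (-1.93, adjusted p = 0.379), Ephx1 (-2.26, adjusted p = 0.396) and Trp53inp1 (-2.81, adjusted p = 0.415). Leaving out p53KO_3dai replicate 1 gave 146 calls, Phlda3 (adjusted p = 0.00476), Trp53inp1 (adjusted p = 0.00955) and Gdf15 (adjusted p = 0.0133) among them, and leaving out p53KO replicate 3 gave 1. A difference in the loss of Trp53 transcript was not called (0.58, SE 0.31, adjusted p = 0.821).

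Does the effect of p53KO differ between G2 and no suffix? The 3 genes called were Snora33 (adjusted p = 5.29e-07), Cdkn3 (adjusted p = 0.019) and Taco1, a translational activator of mitochondria (adjusted p = 0.0493), each lower. Taco1 was listed at 0 in the 3 p53WT libraries and at 2.54, 1.32 and 2.76 FPKM in p53KO, against 11.2 and 11.9 in p53WT_G2 and 2.87 and 1.61 in p53KO_G2, and Cdkn3 was listed at 0 in all 6 libraries with no suffix. By limma's test 564 genes had an unadjusted p under 0.05. Ccng1 (-2.05, SE 0.40, adjusted p = 0.239), Polk (-1.80, adjusted p = 0.591), Zmat3 (-1.55, adjusted p = 0.633) and Trp53 (0.59, SE 0.34, adjusted p = 1) did not pass. Snora33 kept its call with any of the 10 libraries left out (adjusted p at most 1.01e-05), and Taco1 lost its call whichever was left out (adjusted p = 0.0528 to 0.292). Cdkn3 lost it in every case (adjusted p = 0.0528 to 0.154) except without p53WT replicate 2 (adjusted p = 0.0438).

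What separates 3dai cells from cells with no suffix, in p53WT and in p53KO? Top2a, the topoisomerase of dividing cells, rose from 1.00 ± 0.751 to 158 ± 28.4 FPKM in p53WT (n = 3 each; log2 difference 6.36, SE 0.27, adjusted p = 2.6e-10) and from 0.999 ± 0.17 to 239 ± 46.7 in p53KO (6.89). Ccna2, the S and G2 phase cyclin, rose from 0.896 ± 0.472 to 146 ± 10.7 (6.30, SE 0.23, adjusted p = 1.08e-10) and from 0.506 ± 0.422 to 174 ± 15.0 (6.89). Eno3, the muscle enolase, rose from 7.68 ± 1.26 to 543 ± 114 (5.96, SE 0.23, adjusted p = 1.19e-10) and from 9.74 ± 3.84 to 640 ± 88.8 (5.95). Gpx3, a secreted glutathione peroxidase, fell in p53WT from 3396 ± 367 to 29.1 ± 1.17 (-6.81, SE 0.30, adjusted p = 3.41e-10). Fam132b, the hormone erythroferrone, fell from 1681 ± 105 to 11.7 ± 2.70 (-7.07, SE 0.43, adjusted p = 5.53e-09) in p53WT and from 1337 ± 384 to 12.2 ± 11.4 (-6.96) in p53KO.

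In p53WT 6823 genes were called, 4122 higher and 2701 lower in 3dai, and in p53KO 6883, 3939 higher and 2944 lower. At 2-fold or more the calls were 3251 higher and 2204 lower in p53WT and 3076 and 2441 in p53KO. The median over all genes was 0.23 and 0.14. The factors of median-of-ratios scaling differ between the groups by 0.41 in p53WT and 0.34 in p53KO on the log2 scale, and with them the median over all genes was -0.064 and -0.090. After it 3040 genes were higher and 3551 lower in p53WT and 3024 and 3701 in p53KO, 46.1% and 45.0% higher in place of 60.4% and 57.2%. The differences ran in parallel in the genotypes (Pearson r = 0.92 across genes, which are not independent replicates). Of them 3373 were higher and 2265 lower in both, where 1253 and 614 would be if the calls were independent, and 4 were called in opposite directions.

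Cell cycle genes rose, and of paired values the first is p53WT and the second p53KO. All 38 mitosis genes were called higher in both genotypes, with medians of 5.16 (adjusted p = 1.5e-25, or 0.0258 with an estimated correlation) and 5.32 (adjusted p = 4.61e-27, 0.0256 estimated). Of the DNA replication genes 37 were higher and 0 lower in both, with medians of 3.69 (adjusted p = 6.92e-19, 0.0258 estimated) and 3.53 (adjusted p = 3.68e-18, 0.0256 estimated). In p53KO Cdk1, the mitotic kinase, rose by 6.33, Anln, of the cleavage furrow, by 6.28 (from 0.485 ± 0.297 to 114 ± 18.2 FPKM) and Cdca3, a mitotic entry factor, by 6.15. Birc5, of the chromosomal passenger complex, rose by 7.06 and 6.35 and Ube2c, which feeds the anaphase ligase, by 6.32 and 7.53. Uhrf1, a reader of methylated DNA, rose by 6.09 and 5.34. Homologous recombination and Fanconi genes (29) were higher as a list, with 24 higher and 1 lower in p53WT (median 2.35, adjusted p = 1.5e-07, 0.0258 estimated) and 22 and 0 in p53KO (2.03, adjusted p = 1.82e-07, 0.0256 estimated). In p53WT Cdk4 rose by 3.25 (SE 0.17, adjusted p = 1.25e-09) to 426.5 ± 4.08 FPKM and Ccnd1, its cyclin, from 14.1 ± 1.17 to 164 ± 33.0 (3.44). Hmga2, a chromatin protein of growing cells, rose by 4.87 and 5.04, and Lmnb1, a lamin that declines in senescence, by 3.42 and 3.51.

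Quiescence genes fell. Of 33, 1 was higher and 26 lower in p53WT (median -3.44, adjusted p = 1.91e-14, or 0.0404 with an estimated correlation) and 1 higher and 29 lower in p53KO, or 30 lower alone (-3.60, adjusted p = 3.4e-16, 0.0286 estimated). Chrdl2, a BMP antagonist, fell by 7.62 on the log2 scale in p53WT and 7.31 in p53KO, Chodl, a membrane lectin, by 7.24 and 6.57, and the Notch effectors Heyl by 4.29 and 4.13 and Hey1 by 3.79 and 3.62. The 16 Notch pathway genes were lower as a list, with 3 higher and 7 lower in p53WT, 8 lower alone (median -0.60, adjusted p = 0.0105, 0.261 estimated), and 2 and 12 in p53KO (-1.25, adjusted p = 0.000662, 0.136 estimated). The ligands Jag2 (2.97 and 2.42) and Dll1 (2.16 and 0.88) rose. Immediate early genes fell, with 0 higher and 27 lower of 28 in p53WT, 28 lower alone (-2.97, adjusted p = 2.93e-16, 0.058 estimated), and 28 lower in p53KO (-3.76, adjusted p = 2.47e-17, 0.0712 estimated). Egr1, an immediate early transcription factor, fell in p53KO from 1251 ± 588 to 11.2 ± 2.27 FPKM (-6.57), and Btg2, an antiproliferative p53 target, from 729 ± 555 to 2.19 ± 0.343 (-7.59, and -6.64 in p53WT). Ctgf, a matricellular growth factor, fell by 6.29 and 7.39 on the log2 scale, Il6 by 4.49 and 5.79, and the chemokine Cxcl2 by 4.80 and 5.84.

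Of 68 oxidative phosphorylation genes 62 were higher and 0 lower in p53WT, 64 alone (median 1.63, adjusted p = 1.63e-13, or 0.243 with an estimated correlation), and 61 and 0 in p53KO, 62 alone (1.70, adjusted p = 1.65e-14, 0.203 estimated). Sdhd of complex II rose by 2.89 in p53WT and Atp5g1 of the ATP synthase by 2.71 and 3.07. Glycolysis genes were higher in p53WT (20 genes, 10 higher and 3 lower, 0.84, adjusted p = 0.0242, 0.261 estimated) and did not pass in p53KO (10 and 5, 0.94, adjusted p = 0.0683). Pgk1, a glycolytic kinase, rose by 2.98 and 3.40 while Pygm, the muscle glycogen phosphorylase, fell by 3.02 and 3.72 on the log2 scale. Ribosomal proteins (59) were higher, with 29 higher and 0 lower in p53WT, 28 alone (0.50, adjusted p = 0.000524, 0.587 estimated), and 23 and 0 in p53KO, 20 alone (0.44, adjusted p = 0.00325, 0.629 estimated). After median-of-ratios scaling they were higher by 0.10 (adjusted p = 0.0758) and 0.11 (adjusted p = 0.138) and did not pass. Muscle differentiation genes (31) did not pass, with 13 higher and 3 lower in p53WT (0.78, adjusted p = 0.162) and 11 and 4 in p53KO (0.68, adjusted p = 0.2). Tnnt2, the cardiac and embryonic troponin T, rose by 4.23 in p53WT and Chrng, the fetal acetylcholine receptor subunit, by 3.93 and 3.95. Activated myoblast genes (-0.55, mean 0.03, adjusted p = 0.311, and -0.51, adjusted p = 0.454) and genes associated with rhabdomyosarcoma (-0.46, adjusted p = 0.214, and -0.67, adjusted p = 0.173) did not pass either. In the latter Igf2, a fetal growth factor, fell by 2.48 and 3.03 on the log2 scale and Fgfr1 by 3.58 and 3.74. Dmd fell by 3.35 on the log2 scale in p53WT, from 17.1 ± 4.09 to 0.739 ± 0.0364 FPKM (adjusted p = 1.89e-07), and by 3.11 in p53KO (adjusted p = 3.73e-07).

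Of extracellular matrix genes 2 were higher and 32 lower in p53WT (median -2.17, adjusted p = 1.89e-13, or 0.0627 with an estimated correlation) and 2 and 30 in p53KO (-2.43, adjusted p = 2.7e-12, 0.0773 estimated). Interferon response genes had 0 higher and 26 lower in each (-1.87, adjusted p = 8.52e-09, 0.058 estimated, and -1.73, adjusted p = 8.52e-08, 0.0731 estimated). Heat shock genes had 4 and 12 in p53WT (-1.58, adjusted p = 0.000707, 0.274 estimated) and 3 and 12 in p53KO, 4 and 12 alone (-2.01, adjusted p = 0.00132, 0.341 estimated). Dpt, a dermal matrix protein, fell by 6.92 on the log2 scale in both, Has1, a hyaluronan synthase, by 4.87 and 4.80, and Gbp2, an interferon-induced GTPase, by 4.87 and 4.89. The metalloprotease inhibitor Timp1 rose by 1.21 and 1.67 and the chaperonin Hspd1 by 1.12 and 1.34. The 18 imprinted genes were lower as a list, with 5 higher and 8 lower in each genotype (-0.62, adjusted p = 0.0186, 0.058 estimated, and -0.66, adjusted p = 0.0249, 0.0731 estimated). Rian, a maternally expressed noncoding RNA, fell in p53WT from 109 ± 8.04 to 1.10 ± 0.771 FPKM (-5.78, and -5.59 in p53KO) and Meg3 from the same locus fell by 5.79 and 6.14 on the log2 scale. H19 rose by 2.44 and 1.71 and Peg10 by 1.64 and 2.04.

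The p53 targets did not pass between 3dai and no suffix (19 higher and 8 lower, median 0.63, adjusted p = 0.24 in p53WT, and 14 and 15, -0.35, adjusted p = 0.2 in p53KO). Trp53 rose by 1.58 (adjusted p = 2.17e-05) and 2.16 (adjusted p = 9.67e-07), Gtse1, which restrains p53, by 4.85 and 3.89, and Ckap2 by 3.85 and 4.37, while Fas fell by 3.81 and 5.24 on the log2 scale. Apoptosis genes (0.84, adjusted p = 0.121, and 0.69, adjusted p = 0.513) did not pass. Senescence genes passed as lower in p53KO (5 higher and 13 lower, -1.55, adjusted p = 0.0154, or 0.371 with an estimated correlation) and not in p53WT (7 and 8, -0.51, adjusted p = 0.161). Cdkn2a, the senescence locus, rose by 3.66 in p53KO.

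Marker lists of several cell types outside the sort fell as well. Whether other cells or the sorted cells made these transcripts, here and in G2, was not tested. The fibro-adipogenic list shares 5 genes with extracellular matrix and the pericyte list 2 with quiescence. Tenocyte markers had 1 higher and 9 lower in each genotype (median -3.37, adjusted p = 7.62e-06, or 0.0258 with an estimated correlation, and -3.58, adjusted p = 1.26e-05, 0.0256 estimated). Scx, the tendon transcription factor, rose by 2.90 and 3.00, and Fmod, a collagen-binding proteoglycan, fell (-4.52 and -4.88). Fibro-adipogenic markers had 0 and 13 in p53WT (-2.67, adjusted p = 2.92e-07, 0.058 estimated) and 0 and 12 in p53KO (-2.66, adjusted p = 8.57e-07, 0.0731 estimated). Pericyte and smooth muscle markers had 0 and 11 in p53WT (-3.39, adjusted p = 5.54e-08, 0.0663 estimated) and 0 and 11 in p53KO, 12 lower alone (-3.24, adjusted p = 2.4e-07, 0.0821 estimated). Schwann cell markers had 0 and 11 in each (-3.04, adjusted p = 1.11e-07, 0.058 estimated, and -2.97, adjusted p = 4.53e-07, 0.0731 estimated). Myh11, the smooth muscle myosin, fell by 6.34 and 5.82 on the log2 scale and Mbp, a myelin protein, by 5.94 and 5.22. Endothelial (-0.65, adjusted p = 0.0551, and -0.27, adjusted p = 0.131), macrophage (-0.47, adjusted p = 0.494, and 0.26, mean -0.11, adjusted p = 0.877) and mature fibre markers (-0.20, adjusted p = 0.204, and -0.29, adjusted p = 0.21) did not pass. Of the sort genes Itga7 rose by 1.11 and 1.26 and Cd34 was not called (-0.45, adjusted p = 0.213, and -0.66, adjusted p = 0.0712). Under median-of-ratios scaling it was (-0.85, adjusted p = 0.0221, and -0.99, adjusted p = 0.0093).

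**Figure D3:**
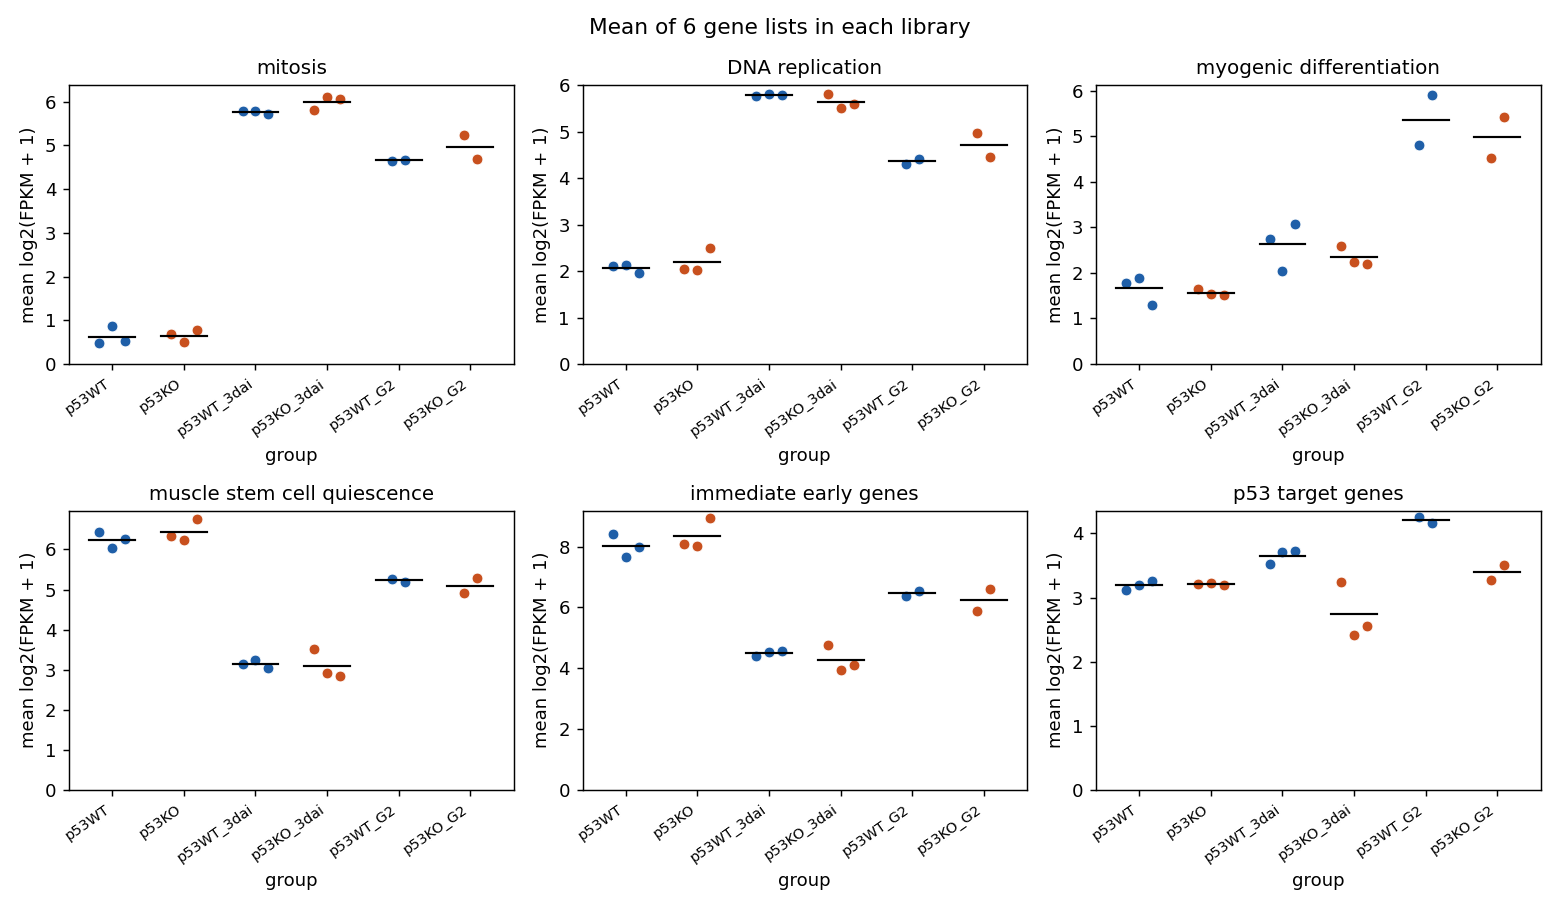
Mean log2(FPKM + 1) over the genes of 6 lists (vertical axis) in each library (points) by group (horizontal axis), blue p53WT and orange p53KO, with a line at the group mean. For the p53 targets the p53KO_3dai libraries lie at 3.24, 2.42 and 2.56.

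What separates G2 cells from cells with no suffix, in p53WT and in p53KO? Myog, the transcription factor of muscle differentiation, rose from 3.60 ± 5.58 to 233 ± 101 FPKM in p53WT (n = 3 and 2; log2 difference 6.34, SE 0.93, adjusted p = 0.000144) and from 3.39 ± 3.98 to 182 ± 65.5 in p53KO (5.75). Myh3, the embryonic myosin, rose in p53WT from 0.178 ± 0.201 to 76.7 ± 54.9 (5.85, SE 0.52, adjusted p = 1.52e-06), and Acta1, skeletal actin, from 16.2 ± 10.9 to 475 ± 262 (4.96, and 3.99 in p53KO). Top2a rose in p53WT from 1.00 ± 0.751 to 80.2 ± 9.71 (5.40), and Ccna2 in p53KO from 0.506 ± 0.422 to 74.6 ± 16.0 (5.67). Myod1, the factor of committed myoblasts, fell from 1105 ± 156 to 192 ± 0.458 in p53WT (-2.50, SE 0.34, adjusted p = 7.77e-05) and from 901 ± 446 to 167 ± 9.51 in p53KO (-2.26).

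In p53WT 3566 genes were called, 2868 higher and 698 lower in G2, and in p53KO 3830, 2916 higher and 914 lower. At 2-fold or more the calls were 2348 and 538, and 2284 and 777. The median over all genes was 0.33 and 0.31. The factors of median-of-ratios scaling differ between the groups by 0.43 on the log2 scale in both genotypes, and with them the median over all genes was 0.00 and -0.027. After it 1642 genes were higher and 1523 lower in p53WT and 1590 and 1641 in p53KO, 51.9% and 49.2% higher in place of 80.4% and 76.1%. Leaving out p53WT_G2 replicate 1 or 2 gave 2302 and 1826 calls in p53WT, and leaving out p53KO_G2 replicate 1 gave 2095 in p53KO. Across genes the differences of the genotypes had Pearson r = 0.80, with 2143 genes higher and 507 lower in both (646 and 49.2 if independent) and 0 opposite, though genes are not independent replicates.

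Of 31 muscle differentiation genes 28 were higher in G2 and 0 lower in p53WT, 29 alone (median 3.26, adjusted p = 2.38e-14, or 0.0903 with an estimated correlation), and 25 and 0 in p53KO, 26 alone (3.30, adjusted p = 1.86e-12, 0.0924 estimated). Mature fibre markers, which share 4 genes with them, were higher too. Of 18, 11 were higher and 0 lower in p53WT, or 11 and 1 alone (1.98, adjusted p = 0.00425, 0.39 estimated), and 9 and 0 in p53KO (1.41, adjusted p = 0.025, 0.513 estimated). Tnnt2 rose by 6.97 and 6.59, Murc, a caveolar protein of muscle, by 5.96 and 5.72, and in p53WT Actc1, cardiac actin, by 6.05, Tnni1, slow troponin I, by 6.02 and Tmem8c, the fusion protein myomaker, by 5.96. All 38 mitosis genes rose in both genotypes (4.03, adjusted p = 3.9e-36, 0.0124 estimated, and 4.31, adjusted p = 7e-37, 0.0115 estimated). DNA replication genes had 33 higher and 0 lower in both, 35 alone in p53KO (2.54, adjusted p = 2.3e-16, 0.0484 estimated, and 2.65, adjusted p = 9.72e-19, 0.0321 estimated). Ube2c rose by 5.34 and 6.55 and Uhrf1 by 4.44 and 4.34. Homologous recombination and Fanconi genes followed, 17 and 0 in p53WT, 20 alone (1.27, adjusted p = 9.17e-05, 0.0903 estimated), and 18 and 0 in p53KO, 19 alone (1.34, adjusted p = 0.000136, 0.0851 estimated). Brca1, of homologous recombination, rose by 2.76 in p53KO.

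The p53 targets were higher in G2 in p53WT (20 higher and 3 lower of 44, 21 and 3 alone, median 0.95, adjusted p = 0.00952, or 0.39 with an estimated correlation). They did not pass in p53KO (13 and 5, 14 and 5 alone, 0.24, adjusted p = 0.733), where the median turns to -0.09 under median-of-ratios scaling. In p53WT Ccng1 rose from 7.72 ± 2.37 to 69.5 ± 1.05 FPKM (3.05, SE 0.28, adjusted p = 1.96e-06), Phlda3 from 13.0 ± 2.68 to 102 ± 4.26 (2.90, and 2.04 in p53KO) and Polk by 2.91. Btg2 fell by 2.91 on the log2 scale and by 4.63 in p53KO. Apoptosis genes were higher in p53WT (11 and 1, 15 and 1 alone, 1.00, adjusted p = 0.0398, 0.223 estimated) and did not pass in p53KO (0.76, adjusted p = 0.278). Casp6, an executioner caspase, rose by 2.64 and 1.85. Senescence genes did not pass (0.29, adjusted p = 0.765, and -0.36, mean 0.35, adjusted p = 0.727). Cdkn2a rose by 5.29 to 67.4 ± 12.3 FPKM and by 6.03 to 86.8 ± 13.5, and Igfbp3, a secreted growth factor binding protein, by 2.76 and 3.12. Trp53 was not called in p53WT (0.46, adjusted p = 0.175) and rose in p53KO (1.05, adjusted p = 0.00461).

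Quiescence genes were lower, with 1 higher and 12 lower in p53WT, 1 and 15 alone (median -1.02, adjusted p = 1.97e-11, or 0.0903 with an estimated correlation), and 1 and 19 in p53KO, 1 and 22 alone (-1.46, adjusted p = 1.79e-13, 0.0632 estimated). Immediate early genes had 0 and 18 in p53WT, 21 lower alone (-1.42, adjusted p = 9.21e-16, 0.0903 estimated), and 0 and 22 in p53KO, 24 alone (-2.14, adjusted p = 9.72e-19, 0.0687 estimated). Heat shock genes had 1 and 9 in p53WT (-1.22, adjusted p = 5.53e-06, 0.252 estimated) and 1 and 12 in p53KO (-1.39, adjusted p = 9.7e-09, 0.116 estimated). Blnk, a B-cell adaptor, fell in p53WT from 38.9 ± 3.50 to 1.48 ± 0.134 FPKM (-4.00, SE 0.41, adjusted p = 4.84e-06) and Gpx3 from 3396 ± 367 to 320 ± 48.3 (-3.41). Clu, the chaperone clusterin, fell in p53KO from 86.8 ± 12.3 to 4.36 ± 0.615 (-4.03, SE 0.52, adjusted p = 5.24e-05). Chrdl2 fell by 3.46 and 3.26 on the log2 scale, Nppc, a natriuretic peptide, by 3.78 and 4.27, Ctgf by 3.32 and 3.16, and the co-chaperone Dnajb1 by 2.58 and 3.86. Notch genes were lower in p53KO (2 and 3, -0.34, adjusted p = 0.0137, 0.309 estimated) and not in p53WT (-0.09, mean 0.14, adjusted p = 0.259). Jag2 rose by 2.47 and 1.28. Dmd fell by 1.93 and 1.86 on the log2 scale.

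Oxidative phosphorylation genes had 49 higher and 0 lower in p53WT, 58 alone (median 1.23, adjusted p = 1.3e-11, or 0.352 with an estimated correlation), and 56 and 0 in p53KO, 60 alone (1.38, adjusted p = 4.35e-14, 0.245 estimated). Glycolysis genes had 12 and 1 in p53WT (0.89, adjusted p = 0.0082, 0.278 estimated) and 11 and 0 in p53KO (0.92, adjusted p = 0.00415, 0.226 estimated). Eno3 rose by 5.31 and 4.70 and Tpi1, an isomerase of glycolysis, by 2.25 and 2.36. Ribosomal proteins did not pass (0.02, adjusted p = 0.106, and 0.04, adjusted p = 0.174) and their direction depends on the scaling, with -0.39 in both after median-of-ratios scaling (adjusted p = 9.03e-05 and 0.000247 at the preset correlation, the estimated one not run there) and 0.18 and 0.14 after quantile normalization. Imprinted genes did not pass (0.27, adjusted p = 0.763, and 0.28, adjusted p = 0.705, with -0.01 and -0.14 scaled) and moved both ways. H19 rose in p53WT from 12.2 ± 6.80 to 257 ± 124 FPKM (4.32, and 3.21 in p53KO) and Mest, a hydrolase, from 39.5 ± 12.7 to 324 ± 99.6 (3.02), while Rian fell by 3.20 and 3.25 on the log2 scale. Activated myoblast genes did not pass (0.24, adjusted p = 0.688, and 0.38, adjusted p = 0.985, with -0.20 and -0.06 scaled). Nor did genes associated with rhabdomyosarcoma (0.14, adjusted p = 0.872, and 0.32, adjusted p = 0.844, with -0.28 and -0.11 scaled) or interferon response genes (0.12, adjusted p = 0.0892, and 0.07, adjusted p = 0.169, with -0.23 and -0.32 scaled). Extracellular matrix genes did not pass (0.30, -0.13 scaled, adjusted p = 0.763, and -0.05, mean 0.13, adjusted p = 0.386), although Tnc, the matrix protein tenascin, rose by 2.95 and 3.43.

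Among cells outside the sort, Schwann cell markers had 0 higher and 8 lower in p53WT (median -1.30, adjusted p = 4.1e-07, or 0.0973 with an estimated correlation) and 0 and 7 in p53KO, 8 alone (-1.51, adjusted p = 2.1e-07, 0.0896 estimated). Fibro-adipogenic markers had 1 and 4 in each (-0.62, adjusted p = 0.00813, 0.352 estimated, and -0.98, adjusted p = 0.000868, 0.227 estimated). Tenocyte markers passed as lower in p53KO (1 and 6, 1 and 7 alone, -1.13, adjusted p = 0.000136, 0.0589 estimated) and not in p53WT (1 and 0, -0.02, mean 0.08, adjusted p = 0.318). So did pericyte markers (0 and 2, -0.46, adjusted p = 0.025, 0.513 estimated) against p53WT (0.01, adjusted p = 0.403), where the median turns to -0.39 under median-of-ratios scaling and -0.21 under quantile normalization. Ncmap, a myelin protein, fell by 2.34 and 2.15 on the log2 scale, Dcn, the proteoglycan decorin, by 1.33 and 2.25, and Chad, of tendon and cartilage, by 3.50 in p53KO. Endothelial (0.44, adjusted p = 0.688, and 0.18, adjusted p = 0.727) and macrophage markers (0.04, adjusted p = 0.531, and -0.09, adjusted p = 0.457) did not pass. Of the sort genes Itga7 rose by 1.57 and 1.41 and Cd34 fell by 1.36 (adjusted p = 0.00643) and 1.18 (adjusted p = 0.014) on the log2 scale.

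Across genes the effect of p53KO with no suffix had Pearson r = 0.05 with that in 3dai and 0.01 with that in G2, and the effects in 3dai and G2 had r = 0.03. Only 1, 11 and 9 of the 12954 genes were called with no suffix, in 3dai and in G2. A low r therefore cannot tell effects that differ from spread between libraries. Trp53 and Ccng1 were the 2 genes called lower in both 3dai and G2. The difference of 3dai from no suffix in p53WT and that of G2 in p53KO, which share no library, had r = 0.74, and 3dai in p53KO with G2 in p53WT had r = 0.70.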

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

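These results stand out because a test of a difference between groups passed: the effect of p53KO was compared between 3dai or G2 and no suffix. For 3dai 0 single genes passed and 5 lists did. The p53 target genes were lower by a median of -0.96 (adjusted p = 1.14e-11, or 0.165 with an estimated correlation), with 0 genes called and 10 lower when adjusted over the list alone. The median was -0.31 without p53KO_3dai replicates 2 and 3 and -1.05 without replicate 1 (adjusted p = 1.2e-13). Mitosis genes were higher (0.25, adjusted p = 0.0243, 0.943 estimated), and senescence genes (-0.47, adjusted p = 0.0243, 0.943 estimated), immediate early genes (-0.70, adjusted p = 0.00766, 0.943 estimated) and apoptosis genes (-0.51, adjusted p = 0.0434, 0.539 estimated) were lower. The senescence list shares 2 genes with the p53 targets, the immediate early list 1 and the apoptosis list 6. Without p53KO_3dai replicates 2 and 3, which leaves 1 library in that group, the medians were 0.062 for mitosis and 0.15 for senescence genes. They were -0.18 for immediate early and -0.068 for apoptosis genes. Without p53KO replicate 3 immediate early genes (adjusted p = 0.769) and apoptosis genes (adjusted p = 0.0866) did not pass, and under median-of-ratios scaling apoptosis genes did not (adjusted p = 0.0518).

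For G2 the genes Snora33 (-6.96, adjusted p = 5.29e-07), Cdkn3 (-3.66, adjusted p = 0.019) and Taco1 (-3.63, adjusted p = 0.0493) passed as lower. Their fitted values are set against libraries listed at 0, so they depend on the pseudocount and are no bound. The p53 target genes were lower (-0.68, adjusted p = 6.31e-11, or 0.0995 with an estimated correlation), with 6 lower alone, and so were tenocyte markers (-1.24, adjusted p = 2.36e-06, 0.0357 estimated). DNA replication genes (0.22, adjusted p = 0.00844, 0.912 estimated) and mitosis genes (0.31, adjusted p = 0.00844, 0.912 estimated) were higher. Notch pathway genes (-0.52, adjusted p = 0.015, 0.861 estimated), immediate early genes (-0.67, adjusted p = 0.00537, 0.912 estimated) and heat shock genes (-0.40, adjusted p = 0.00558, 0.912 estimated) were lower. Without p53KO replicate 3 these 3 lists did not pass (adjusted p = 0.234, 0.296 and 0.0951). The cause of these list differences was not tested further, except for the p53 targets.

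The p53 target genes were lower with p53KO in 3dai (adjusted p = 0.0511 with an estimated correlation, so not past the limit there) and G2 (0.0252) and not with no suffix; the rank correlations were set before their result was seen, and the other tests after. If the Trp53 transcript were lost less completely in the p53KO libraries with no suffix, the interaction for Trp53 would be negative, but it was 0.58 and 0.59, each above 0 by more than 1 SE and neither called, which argues against it. If p53KO replicate 3 hides a fall with no suffix, the median without it should be at or under -0.40, but it was 0 (interval over genes -0.09 to 0.07). The list mean of log2(FPKM + 1) was 3.215 and 3.23 in p53KO replicates 1 and 2 and 3.115 to 3.255 in p53WT. These values argue against that too. A link in which target genes higher in p53WT_G2 are those that fall with p53KO in 3dai had rank correlation -0.0879 over 44 genes (permutation p = 0.570), and the same link from p53WT_3dai to p53KO in G2 had -0.0871 (permutation p = 0.572), so neither was told from no link. Whether p53 acts on these genes more in 3dai and G2 cells than in cells with no suffix stays open, as no measure of p53 protein or of its binding was used here.

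Snora33 and Cdkn3 were lower with p53KO in G2, and Taco1 passed only in the interaction; the test of Rps12 was set before its result was seen, and the other tests after. Less Rps12 host transcript could lower Snora33, which lies inside Rps12 on the same strand of chromosome 10 (mm10), but Rps12 differed by -0.0078 (SE 0.34, adjusted p = 1), which argues against it. Fewer dividing cells in p53KO_G2 could lower Cdkn3, but the mitosis genes were higher by a median of 0.28 (interval 0.24 to 0.42 over 38 genes, which are not independent, and adjusted p = 0.516 with an estimated correlation). The rise came from replicate 1, but neither p53KO_G2 library (5.24 and 4.69) lay under the p53WT_G2 libraries (4.64 and 4.68), which argues against fewer dividing cells. For values at exactly 0 that arise without regard to group, 5 other genes were at 0 in both p53KO_G2 libraries and above 5 FPKM in both p53WT_G2 libraries, against 0 the other way (exact binomial p = 0.0625, the smallest that 5 genes can give, so the test could not pass), and for Snora33 this stays open. The count does not bear on Taco1, which was at 2.87 and 1.61 FPKM in p53KO_G2 and listed at 0 in the p53WT libraries with no suffix, nor on Cdkn3, at 0 and 0.0844. An effect of p53 on these transcripts stays open and was not tested.

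In 3dai, p53KO_3dai replicates 2 and 3 lay apart from replicate 1, and every test of this was chosen after the result was seen. If the Mir6236 share of the FPKM sum lowered every other gene, the p53 target genes should not be lower once small RNA names are left out. But replicates 2 and 3 stayed lower by a median of -0.51 (interval over genes -0.89 to -0.22, and -0.49 as deposited), which argues against it. This bears only on a lowering through the FPKM sum. Why the Mir6236 share was high in these libraries, and what else goes with it, was not tested. Less complete loss of total Trp53 transcript in replicate 1 is argued against by its 41.3 FPKM, between the 45.7 and 34.9 of the others. This value over the whole gene cannot tell intact transcript from what the knockout leaves. Whether some cells of replicate 1 kept working Trp53 therefore stays open. Its p53 targets were higher as a list (mean log2(FPKM + 1) 3.24 against 2.42 and 2.56), Plk2, Sesn2, Eda2r and Fas among them. Not every target was higher. Ccng1 differed from p53WT_3dai by -1.73, -1.74 and -1.96 without replicate 1, 2 or 3, so it was not higher in replicate 1. Mdm2 in replicate 1 lay near its values in replicates 2 and 3. Cells of replicate 1 handled differently before lysis, with more immediate early transcript, remain possible. Those genes were lower in replicates 2 and 3 by a median of -0.89 (interval over genes -1.12 to -0.03), 19 of 27 of them lower. Schwann cell, pericyte and extracellular matrix genes were lower in replicates 2 and 3 too. Over all genes replicates 2 and 3 stood apart, as replicate 1 had Pearson r of 0.9734, 0.9778 and 0.9674 with p53WT_3dai and 0.960 and 0.9626 with them. They had 0.9787 with each other and 0.9569 to 0.9675 with p53WT_3dai. They also stood apart in senescence genes (2.77 and 2.80, 4.03 in replicate 1, 3.68 to 4.21 in p53WT_3dai) and heat shock genes (7.50 and 7.55, 6.70, and 6.70 to 6.82). Replicate 1 stood above p53WT_3dai in immediate early genes (4.76 against 4.40 to 4.55) and Schwann cell markers (2.16 against 0.991 to 1.37). It did so in extracellular matrix genes too (4.23 against 3.48 to 3.85), so neither side matched p53WT_3dai in every list. A biological difference between the sources of these libraries stays open and was not tested.

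Each count was compared with the other splits of the same libraries into groups of equal size. With no suffix 4 of 10 splits called as many genes as the real 1, with 1 as the highest other. In 3dai 2 of 10 splits did, the real count being 11 and the highest other split 20. That split set p53WT_3dai replicates 1 and 2 with p53KO_3dai replicate 1 against the rest, and the p53 target median had 1 of 10 splits as far from 0, with -0.80 in the real split and 0.54 as the farthest other. For 3dai against no suffix 1 of 10 splits reached the real count in each genotype, 6823 against a highest other of 0 in p53WT and 6883 against 3 in p53KO. For all of these the splits are too few for a share under 0.05. For the interaction in 3dai 100 of 100 drawn splits called at least the real 0, with a highest of 4, which any split must, so this says nothing about chance. Of the medians of the p53 target genes in that interaction 3 of 100 splits, the real one included, lay as far from 0 as the real -0.96. The farthest other was 1.05, farther than the real one, and the list test did not pass with an estimated correlation (adjusted p = 0.165). Some of these splits kept the real 3dai groups and changed only those with no suffix, so they still hold the 3dai difference. The 3 of 100 is therefore no measure of chance, and chance is not ruled out.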

How the results depend on the processing

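Of the gene counts compared across settings 108 stayed within a factor of 1.5 and 45 moved; of the named gene values 6243 kept direction and call, 347 lost the call, 19 gained it and 38 changed direction; of the list values 187 were the same, 101 weaker and 2 reversed. For 3dai against no suffix in p53KO the count with p53KO_3dai replicate 1 alone in its group was 4545, where fewer libraries and a lone library assumed to vary like the other groups bear on it. For G2 against no suffix in p53KO only the groups compared gave 2112 genes, and single libraries left out gave 2095 (p53KO_G2 replicate 1) to 3702 (p53KO replicate 3); in p53WT 1826 (p53WT_G2 replicate 2) to 3199 (p53WT replicate 2). For p53KO against p53WT with no suffix the counts were 2 with array weights, 3 with no filter on low values, 0 with only the groups compared and 5 with a pseudocount of 0.1. In 3dai they were 804 with array weights, 1 with only the groups compared, 3 with replicate 1 alone (in both of these 0 of the 11 genes, Trp53 and Phlda3 included, were called), 17 with the pseudocount and 7 with the replicate block, and 2 (without p53WT_3dai replicate 3) to 512 (without p53KO_3dai replicate 1) with single libraries left out. In G2 they were 5 with array weights, 4 at a mean FPKM of at least 5, 22 with no filter, 0 with only the groups compared and 5 with the replicate block, and 3 (without p53WT_G2 replicate 1) to 6 (without p53KO_G2 replicate 2). The interaction in 3dai called 1 with array weights, 1 with no filter and 1 with the pseudocount, and 0 (without p53KO replicate 1) to 146 (without p53KO_3dai replicate 1). The interaction in G2 called 1 at a mean FPKM of at least 5, 10 with no filter, 5 with only the groups compared, 5 with the pseudocount and 1 with small RNA names left out, and 1 (without p53KO replicate 1) to 3 (without p53WT replicate 2, 2 of them among the 3 called with all libraries). The main fit shares its estimate of spread over all groups, so its p does not measure the spread of the compared groups alone. A fit of only the groups compared has fewer libraries to measure spread from and takes it from those groups alone. Which of these moved the counts was not tested, nor was the cause for the other settings. With FAIL and LOWDATA values missing the genotype counts were the same (1, 11 and 9). Deviations from the group mean were correlated between libraries of the same replicate number in different groups. These correlations of -0.159 to 0.127 give no sign that the numbers pair the libraries. Pairs of different numbers were not compared, and the labels do not say. The alternative without symbols listed more than once is void, as 0 symbols were.

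Apart from Cx3cr1, genes that changed direction were not called, and the cause was not tested. With no suffix Dmd was -0.039 with array weights, Itga7 0.013 with quantile normalization and Pecam1 0.085 with the pseudocount of 0.1. In 3dai Itga7 was -0.12 with p53KO_3dai replicate 1 alone and Pecam1 -0.014 with quantile normalization. Cx3cr1, called higher in 3dai against no suffix in p53KO, was -0.17 with p53KO_3dai replicate 1 alone, and Pecam1 in G2 against no suffix in p53WT was -0.13 with quantile normalization. In the 3dai interaction Cd34 was 0.16 and Itga7 -0.043 with p53KO_3dai replicate 1 alone and Pecam1 -0.085 with the pseudocount, and in the G2 interaction Pecam1 was 0.29 with quantile normalization. With single libraries left out the ranges were: Dmd -0.080 to 0.25 with no suffix, -0.12 to 0.50 in G2 and -0.24 to 0.39 in the G2 interaction; Pecam1 -0.49 to 0.33 with no suffix, -0.87 to 0.32 in G2, -0.30 to 0.89 and -0.27 to 0.74 for G2 against no suffix in p53WT and p53KO, -0.33 to 0.49 and -0.66 to 0.54 in the 3dai and G2 interactions. Ly6a ran from -0.75 to 0.21 with no suffix, -0.21 to 1.57 for G2 against no suffix in p53KO, and -1.32 to 0.14 and -1.48 to 0.30 in the interactions. Itga7 ran from -0.64 to 0.18 in G2 and -0.56 to 0.25 in its interaction, and Cd34 from -0.39 to 0.073 and -0.32 to 0.68 in the 3dai and G2 interactions. Of the lists, heat shock in 3dai ran from -0.049 (without p53KO_3dai replicates 2 and 3) to 0.30, and senescence in the 3dai interaction from -0.83 to 0.15 (without the same libraries). Of the list results 93 passed at the preset correlation and 17 of them held with an estimated correlation, the smallest at adjusted p = 0.00936. Depth is unknown from the files, so how far a 0 or a low FPKM is limited by it cannot be said.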

Other observations

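G2 cells were also compared with 3dai cells, a comparison added after the data were examined, in which the muscle differs too and no list test was run. Muscle differentiation genes were higher in G2, 27 higher and 0 lower of 31 in p53WT (median 2.72) and 23 and 0 in p53KO (2.91). Acta1, skeletal actin, rose by 4.33 (SE 0.62, adjusted p = 0.000215) and 3.85 (adjusted p = 0.000529), Myh3, the embryonic myosin, by 3.29 (SE 0.52, adjusted p = 0.000513) and 3.40 (adjusted p = 0.000376), and Myog by 3.35 (SE 0.93, adjusted p = 0.0184) and 2.83 (adjusted p = 0.0378). Proliferation genes were lower, DNA replication 0 higher and 32 lower in p53WT (-1.38) and 0 and 16 in p53KO (-0.98), mitosis 0 and 25 (-1.06) and 0 and 22 (-1.06). Ccna2, a cyclin of dividing cells, fell in both (SE 0.26, adjusted p = 0.00104 in p53WT), Cdk1 fell by 1.41 and 1.49 on the log2 scale, Top2a by 0.96 and 1.30, and the proliferation marker Mki67 by 0.99 (adjusted p = 0.0487) and 1.12 (adjusted p = 0.0256). In p53WT 2673 genes were called, 1805 higher and 868 lower in G2, and in p53KO 3004, 2084 higher and 920 lower.

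Quiescence genes were higher in G2 than in 3dai (25 higher and 1 lower of 33, median 2.44 in p53WT, and 25 and 0, 2.11 in p53KO), as were extracellular matrix genes (29 and 0 in each, 2.49 and 2.50), interferon response genes (25 and 0, 1.97, and 24 and 0, 1.86) and immediate early genes (19 and 0, 1.99, and 23 and 0, 1.94). Igf2, a fetal growth factor, rose by 4.04 (SE 0.30, adjusted p = 9.15e-07) and 4.25 (adjusted p = 1.71e-06), the imprinted RNAs Meg3 by 3.15 and 3.22 and Rian by 2.58 and 2.34, and Cdkn1c, a cell cycle inhibitor, by 2.66 and 3.54, while Peg10 fell by 1.41 and 1.62 on the log2 scale. Of the senescence genes, 10 were higher and 1 lower in p53WT (0.69) and 12 and 1 in p53KO (1.71), with Cdkn2a up by 2.34 (SE 0.51, adjusted p = 0.00442) and 2.36 (adjusted p = 0.00388), Il6 by 5.56 and 5.44 and Igfbp7, a secreted binding protein, by 3.43 and 4.12. The p53 targets had 8 higher and 0 lower (0.43) and 10 and 3 (0.51). Of markers of other cells, some lists were higher, with pericyte 11 and 0 (3.28) and 10 and 0 (2.99), tenocyte 8 and 0 (2.96) and 6 and 0 (1.65), and fibro-adipogenic 8 and 0 (1.89) and 9 and 0 (1.80). Macrophage markers had 0 and 1 (0.60) and 0 and 0 (-0.24), and adipocyte markers 1 and 0 (0.10) and 2 and 1 (0.43).

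A hypothesis, tested after the result was seen, is that mature fibre RNA carried into the G2 libraries could raise the differentiation genes in G2 over 3dai, although a sort for CD34 and alpha-7 integrin would leave out whole fibres. Fibre markers outside the differentiation list were higher by a median of 1.98 in p53WT (interval over 14 genes 1.18 to 2.46) and 1.60 in p53KO (0.35 to 2.89). The differentiation genes had 2.72 (2.51 to 3.33) and 2.91 (2.06 to 3.40). Carried fibre RNA and differentiation of the sorted cells cannot be told apart by this test.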
